A study of Drosophila melanogaster with 8 samples.

How the data were processed

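Messenger RNA levels were measured in heads of the fruit fly Drosophila melanogaster by 3′ RNA-seq, which counts reads near the 3′ ends of transcripts. Per the labels, the flies were raised at 25 °C under 12 hours of light and 12 hours of dark, kept for 3 more days after CO2 exposure, and collected on dry ice. Total RNA was extracted with TRI Reagent, and pooled, barcoded libraries were made after the RNAtag-Seq protocol, per the labels' protocols. The genotype labels gave 3 groups: Actin-gal4/+ control flies (3 libraries), and flies of 2 RNAi lines against the gene row, row_RNAi1 (2 libraries) and row_RNAi2 (3 libraries). Gal4 is a yeast transcription factor that, placed under the Actin promoter, drives a UAS transgene in most tissues, and the transgene here makes a hairpin RNA against row. The control label names no UAS insertion, so the genetic background of each RNAi line differs from that of the control along with the knockdown. The labels do not say whether libraries of a group came from separate collections of flies, and p-values therefore measure the spread between these samples, which may be technical. Sex and age were not given in the sources used here.

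The authors deposited a single table of raw counts, with whole numbers of reads for 13781 gene symbols in the 8 libraries. The submitters' processing notes name the aligner STAR and the genome build dm3, without versions. The counting program, the gene annotation, the treatment of strand and any molecular identifiers were not given in the sources used here. Without stated strand use, reads of overlapping or antisense genes may not be separated, and near-identical family members may share reads. All 8 count columns matched a sample by name. A symbol read as "nan" was kept as text. Of the symbols, 10981 equalled a symbol in the RefSeq table of the Release 6 assembly, 2704 matched through a synonym and 96 did not match. That table belongs to a later build than dm3, so it served only for names and for which genes neighbour each other, and no coordinates were used. Gene symbols are given as deposited, with the current symbol where it differs. A total of 50 symbols shared all 8 counts with another symbol among the 9560 symbols with over 50 counts in total.

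Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM, whose factors ran from 0.921 to 1.09, low-count genes were removed with filterByExpr, and 9442 genes were tested. A 3-group model was fitted to all 8 libraries, because row_RNAi1 has 2 libraries and the spread was best shared. Quasi-likelihood F tests gave 4 contrasts: row_RNAi1 minus control, row_RNAi2 minus control, the mean of both lines minus control, and row_RNAi2 minus row_RNAi1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Levels are CPM, counts scaled to a common library size on TMM-scaled totals, given as mean ± SD over libraries. Fold changes are log2, from the fit, with standard errors (SE) derived from the F statistic. The level of row was also compared by exact two-sided permutation tests of CPM.

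The genes named in the text were set by a rule written before the data were examined. The rule took row, and the 12 largest changes each way on average among genes called in both lines in the same direction, with a mean of at least 5 CPM and with all 5 knockdown libraries on the same side of all 3 control libraries. It also took the 5 largest each way in each line and between the lines with at least 5 CPM, up to 4 members of each gene list with the smallest p, and all listed partners of ROW and all transgene marker genes. Named genes outside it are said to be chosen after their values were seen. A set of 26 gene lists for pathways, complexes, cell types and tissues was fixed at the same time. It held 389 exact symbols, of which 28 were not found, and several symbol prefixes, from which 2 symbols that belong to other gene families were left out. The 24 lists with at least 3 tested members were tested with camera in limma 3.58.1 on voom weights, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera compares a list's genes with all other genes. Each list was tested again with an estimated correlation, and with fry, which asks whether the genes of a list move, on balance, in 1 direction. Member counts are given over all genes tested and adjusted over the list alone.

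Both lines were compared with the same 3 control libraries. All 8 libraries were therefore simulated 20 times with no change, from the mean control level and fitted spread of each gene. This gave the overlap and correlation that arise with no effect when 3 simulated controls are shared. Genes were drawn independently, so deviations that many genes share within a real control library are absent from the simulation. The real controls were also split between the lines in all 6 ways, 1 library for a line and the other 2 for the other. This leaves 1 part without a replicate of its own. Replicate numbers are shared between groups, but nothing says what a number marks, so the numbers were not used as a block in the reported values. Alternatives planned beforehand were DESeq2 1.42.0, limma voom, other scalings, other filters on low counts, fits to the compared groups alone, the replicate number as a block, counts thinned to the smallest library and leaving out each library in turn. A collapse of symbols with identical counts, a fit without control replicates 2 and 3, and the split of the controls were chosen after seeing the data. Where an alternative leaves 1 library in row_RNAi1 or among the controls, that library is assumed to vary like those of the other groups. The fit without control replicates 2 and 3 rests on a single control library in this way.

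The scripts were tested on simulated counts for 9333 genes with the real means and library sizes, in which 50 genes were changed at each of 4 fold sizes. At a 1.5-fold change 60% of them were recovered for row_RNAi1, 58% for row_RNAi2 and 68% for the average. At a 2-fold change 90%, 88% and 92% were recovered, in the same order. False calls were 20 of 212, 10 of 199 and 13 of 213 in these contrasts, and 6 genes were called between the lines, where none differed. A simulated list of 30 genes raised 1.5-fold was called, and 0 of 20 unchanged lists were called. The library totals ran from 6230666 to 18046699 counts, so 1 count stood for 0.0578 to 0.164 CPM, and the limit that a count of 0 allows (3 counts) stood for 0.173 to 0.492 CPM per library. Intervals on ratios of counts are 95% and cover counting error alone, since reads copied by PCR are not independent molecules.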

Results

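The data comprised 8 libraries of fly heads, 3 from Actin-gal4/+ controls, 2 from row_RNAi1 and 3 from row_RNAi2. The gene row (relative of woc) encodes a zinc-finger chromatin protein, and the series asks which genes depend on it together with the architectural factor BEAF-32. The controls held 7015874, 9437287 and 8974606 counts (replicates 1 to 3), row_RNAi1 held 17952015 and 18046699, and row_RNAi2 held 6230666, 11212213 and 10678460. Between 10945 and 12017 genes had at least 1 count in a library, and the 10 most abundant genes took 16.8% to 22.0% of counts. The yolk protein gene Yp1 alone took 3.39% to 4.94%. Within a group, log2 CPM correlated across genes at 0.983 to 0.992, and no pair of libraries differed by as little as sampling noise (chi-square over degrees of freedom 5.97 to 10.3). The first principal component held 50.3% of the variance and the next 15.7%.

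The transcript of row was lower in both RNAi lines. It stood at 13.7 ± 1.49 CPM in controls (SD, n = 3), 5.08 ± 1.21 CPM in row_RNAi1 (SD, n = 2) and 7.43 ± 1.27 CPM in row_RNAi2 (SD, n = 3), or 36.9% and 54.0% of the control mean. All 5 knockdown libraries (4.22 to 8.28 CPM) lay below all 3 control libraries (12.1 to 14.9 CPM), as the plot of row CPM by group shows. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave a log2 fold change of -1.44 (SE 0.19, adjusted p = 1.81e-05) in row_RNAi1 and -0.90 (SE 0.17, adjusted p = 0.00175) in row_RNAi2. Over both lines the change was -1.17 (SE 0.15, adjusted p = 1.80e-05), and an exact two-sided permutation test of the 5 knockdown against the 3 control libraries gave p = 0.0179, the smallest of its 56 arrangements. For a single line the exact permutation test cannot go below p = 0.1, which both lines reached. The difference between the lines, 0.54 (SE 0.20), did not pass the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.104). Reads of the hairpin itself, if counted, would add to these values.

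**Figure D1:**
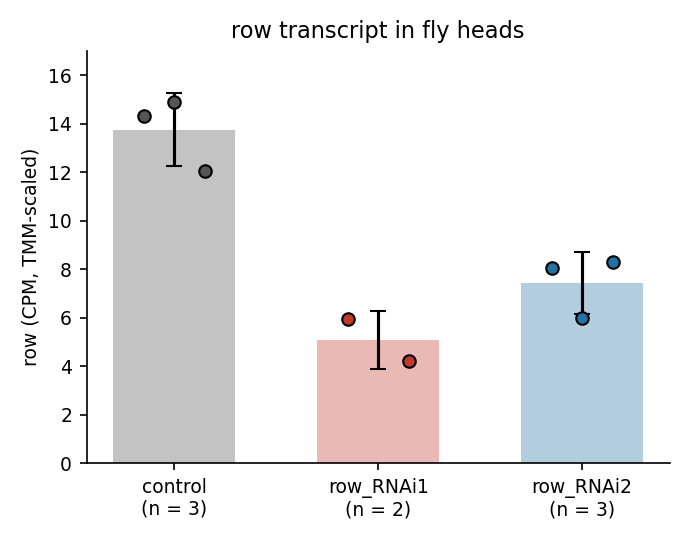
Level of the row transcript in CPM (TMM-scaled, linear axis from 0) in control, row_RNAi1 and row_RNAi2 heads. Bars are means, error bars SD and points single libraries, and all 5 knockdown points lie below the lowest control point of 12.1 CPM.

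The first comparison asks which transcripts changed in heads of both knockdown lines. Among the named genes that rose were the lysozyme genes LysS and LysP, the cuticle protein gene Cpr64Ac, and the genes CG45080, CG13947, CG16826, CG1678 (whe), CG34212, CG44142, CG43680, CG43679 and CG33109. CG45080 went from 12.8 ± 16.5 CPM in controls (SD, n = 3) to 1467 ± 432 in row_RNAi1 (SD, n = 2) and 670 ± 247 in row_RNAi2 (SD, n = 3), and CG1678 from 40.7 ± 64.5 to 1916 ± 740.5 and 1013 ± 406 CPM. Cpr64Ac rose from 0.718 ± 0.408 CPM to 36.1 ± 6.09 and 9.29 ± 0.391 CPM. Its average log2 fold change was 4.72 (SE 0.23, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 1.09e-10). LysS had 2 counts over all controls against 983 in row_RNAi1 and 127 in row_RNAi2, ratios of 381 (95% counting interval 105 to 3154) and 58.7 (15.9 to 490) in scaled counts. The average log2 fold changes of the other 10 rising genes ran from 4.78 (CG34212) to 6.45 (CG44142), with 5.55 for LysP. LysS and LysP belong to a family of close paralogs, and reads could be shared among them.

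The rise of 9 of these genes (CG45080, CG13947, CG16826, CG1678, CG34212, CG44142, CG43680, CG43679 and CG33109) also showed in control replicate 2. Their median level was 0.525, 15.7 and 0.447 CPM in control replicates 1 to 3, 245 and 205 CPM in row_RNAi1, and 81.4, 147 and 124 CPM in row_RNAi2. Without control replicate 2 their average log2 fold changes were larger, at 8.27 for CG45080, 9.23 for CG13947, 8.51 for CG16826, 8.68 for CG1678, 8.37 for CG34212, 9.16 for CG44142, 9.24 for CG43680, 6.84 for CG43679 and 6.80 for CG33109. LysP then stood at 6.81. The plot of levels per library shows the 9 genes beside a set of antennal markers.

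**Figure D2:**
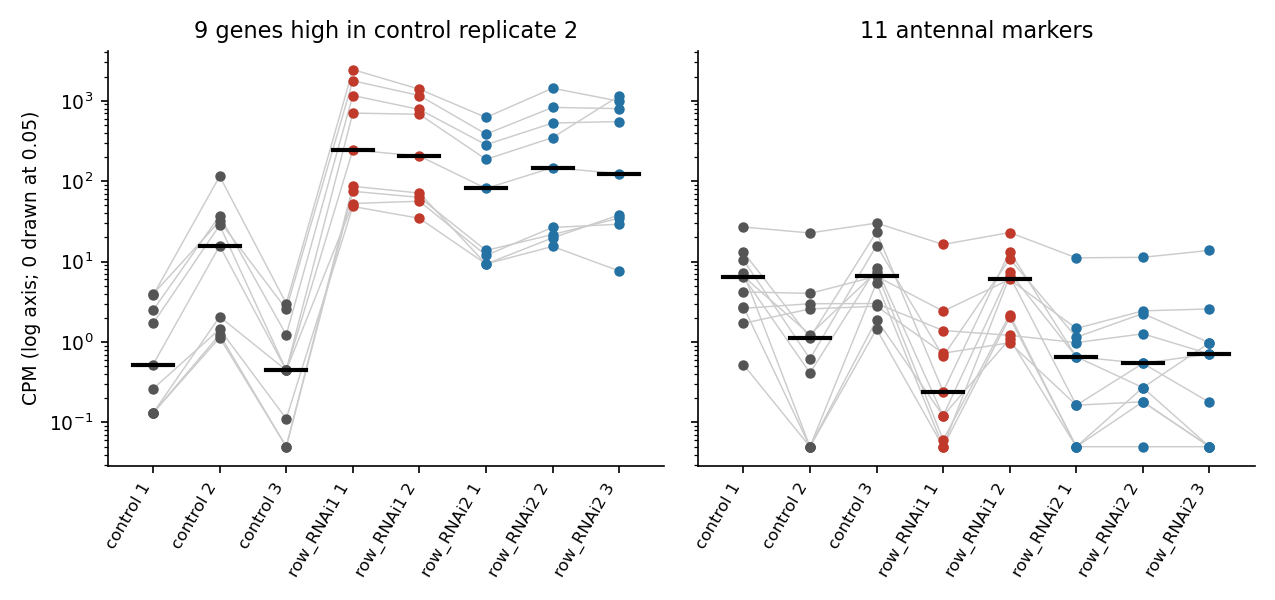
Level in CPM (log axis, 0 drawn at 0.05) of 9 genes that were at least 4 times higher in control replicate 2 than in both other controls (left) and of 11 antennal markers (right), in each of the 8 libraries. Points are genes joined by grey lines and bars are medians; in control replicate 2 the medians were 15.7 CPM on the left and 1.14 CPM on the right.

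Genes that fell in both lines included CG10814, CG8147 (phu, annotated as an alkaline phosphatase), CG9507 (Nepl5, a neprilysin-like metallopeptidase) and Orct2, an organic cation transporter. CG10814 went from 219 ± 44.4 CPM in controls (SD, n = 3) to 3.88 ± 2.13 in row_RNAi1 (SD, n = 2) and 4.16 ± 2.69 in row_RNAi2 (SD, n = 3), an average log2 fold change of -5.85 (SE 0.23, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 1.18e-11). CG8147 went from 599 ± 70.2 to 9.43 ± 3.58 and 26.3 ± 9.99 CPM. CG9507 went from 38.1 ± 3.14 to 1.201 ± 0.671 and 5.90 ± 1.43 CPM, and Orct2 from 24.4 ± 2.07 to 3.71 ± 0.965 and 2.88 ± 0.26 CPM. CG40298, CG3397, CG9377, CG40470, CG34305, CG4757, CG3270 and CG10962 also fell, with average log2 fold changes from -3.96 (CG40298) to -2.65 (CG10962). CG10962 overlaps CR43836, and its reads may be partly shared. Without row_RNAi1 replicate 1 the change of CG10814 in row_RNAi1 went from -5.83 to -6.53.

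In all, 768 genes changed in the same direction in both lines, 397 up and 371 down, and 22 in opposite directions. Each line's edgeR quasi-likelihood calls used a Benjamini-Hochberg adjusted p under 0.05. Another 1211 genes were called in row_RNAi1 alone and 232 in row_RNAi2 alone. Independent lists of these sizes would share 57.9 rising and 50.5 falling genes. Simulated unchanged groups with 3 simulated controls in common shared 0.4 genes on average and 4 at most. Of 7438 tested genes with at least 5 CPM, all 5 knockdown libraries lay on 1 side of all 3 controls for 1368, or 18.4%, an arrangement that chance gives in 3.57% of cases for a gene. Among the 671 shared genes of that level, which were selected by their change, 348 rising and 313 falling genes had it. The shared calls made up 75.1% of those in row_RNAi2, and 601 of the 768 changed more in row_RNAi1, with a median ratio of 0.739 between the log2 fold changes (row_RNAi2 over row_RNAi1). Across genes, which are not independent replicates, the log2 fold changes of the lines correlated with Pearson's r of 0.775 and Spearman's rho of 0.596, against 0.505 and 0.458 for simulated unchanged groups. The covariance was 0.278 against 0.0255 simulated, a difference of 0.252. Part of the excess of shared genes over independent lists may come from the shared controls. With the controls split between the lines in all 6 ways, 1 library for a line and 2 for the other, 420 to 567 genes were shared, Pearson's r ran from 0.535 to 0.644 and the covariance from 0.234 to 0.267. With control replicate 1 as the single control, 424 genes were shared.

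**Figure D3:**
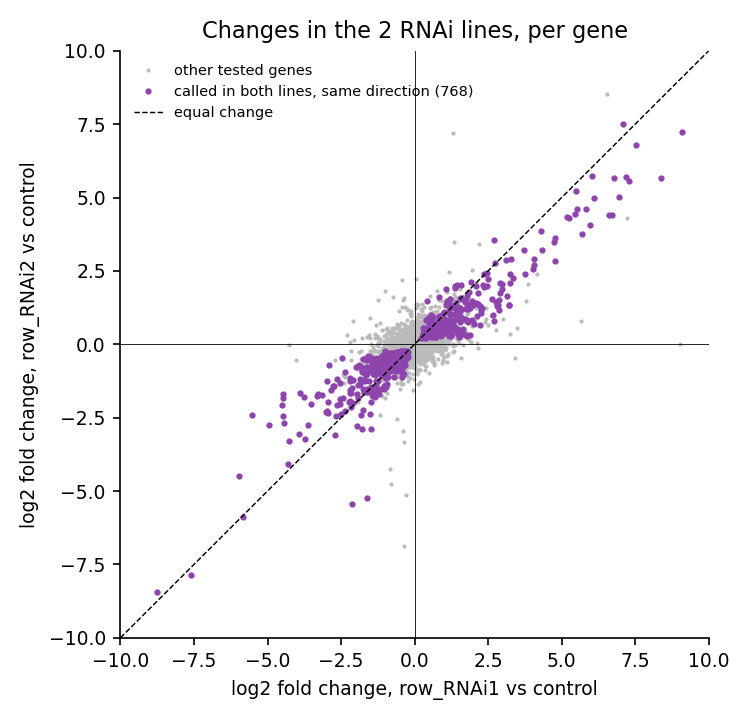
Log2 fold change against control in row_RNAi2 (vertical) plotted against that in row_RNAi1 (horizontal), 1 point per tested gene, with the dashed line marking equal change. Purple points are the 768 genes called in both lines in the same direction, of which 601 changed more in row_RNAi1.

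Averaged over the lines, 1680 of 9442 tested genes changed, 872 up and 808 down, and 357 of them by more than 1 on the log2 scale (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The median log2 fold change of all genes was -0.01. A model with all 5 knockdown libraries as 1 group called 834 genes, and leaving out control replicates 2 and 3, which leaves a single control, gave 883. Of the genes named as list members, that 1-group model no longer called IM4 (0.118), IM14 (0.126), TotC (0.0576), Rh3 (0.100), ple (0.0587), Gat (0.0508), Tret1-1 (0.314), ImpL3 (0.0598), ATPsyngamma (0.105), Hsp67Ba (0.0976), roX1 (0.275) and w (0.341), with edgeR quasi-likelihood Benjamini-Hochberg adjusted p in brackets. DESeq2 did not call Hsp67Ba (0.0560), roX1 (0.132) or w (0.116).

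Genes of the humoral immune response rose as a group. Of 30 tested antimicrobial peptide, Bomanin and recognition genes, 27 rose on average over the lines (28 adjusted over the list alone), with a median log2 fold change of 1.01. The antifungal peptide gene Drosomycin (Drs) rose from 129 ± 2.84 CPM in controls (SD, n = 3) to 875 ± 128 in row_RNAi1 (SD, n = 2) and 352 ± 46 in row_RNAi2 (SD, n = 3), and Defensin (Def) from 30.2 ± 5.6 to 224 ± 18.4 and 129 ± 7.83 CPM. The average log2 fold changes were 2.10 for Drs, 2.50 for Def, 1.03 for IM4 (Dso1) and 0.88 for IM14 (Dso2). The last 2 averages came mostly from row_RNAi1, with 1.79 there and 0.28 in row_RNAi2 for IM4, and 1.51 and 0.25 for IM14. The list passed camera with an adjusted p = 4.08e-26, and had an adjusted p = 0.0913 with an estimated correlation. Of 7 stress-induced Turandot and JAK-STAT target genes 3 rose too (4 adjusted over the list alone), with a median log2 fold change of 0.29 over the list. The average log2 fold changes were 1.39 for TotA, 1.84 for TotM and 1.37 for TotC. This list had a camera adjusted p = 0.000337 and an adjusted p = 0.0913 with an estimated correlation.

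**Figure D4:**
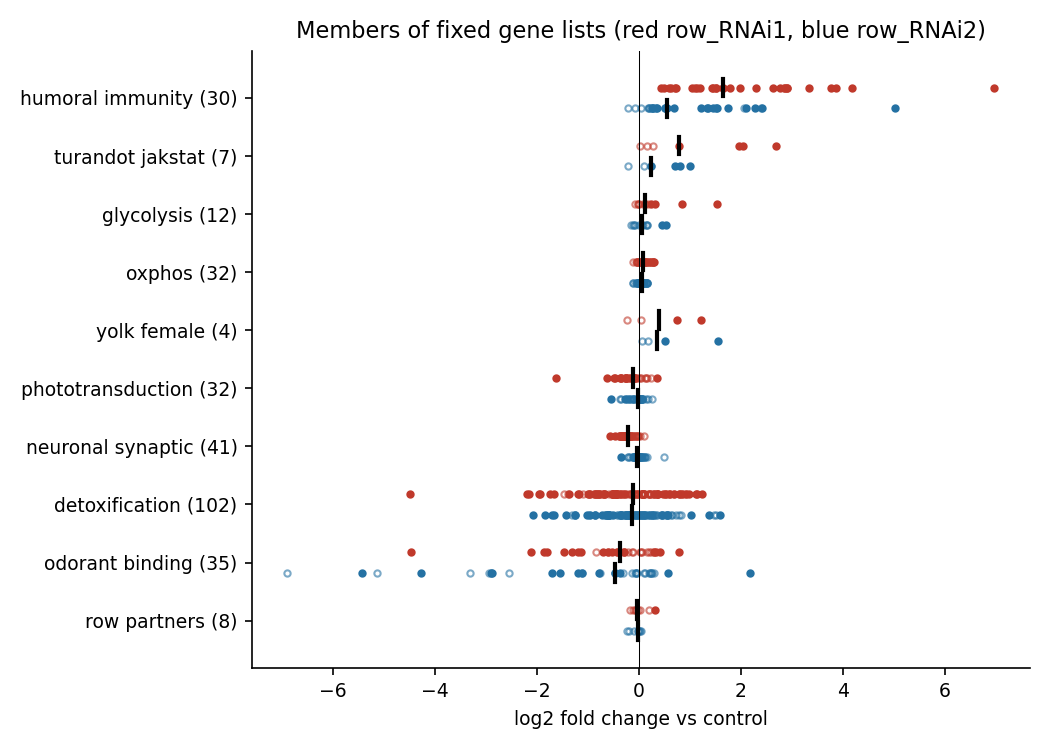
Log2 fold change against control (horizontal) of each tested member of 10 gene lists, red for row_RNAi1 and blue for row_RNAi2, with the number of tested members in brackets. Filled points passed the edgeR quasi-likelihood test for that line, open points did not, and black bars are medians, which for humoral immunity stood at 1.64 in row_RNAi1 and 0.54 in row_RNAi2.

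Detoxification genes moved both ways. Of 102 tested cytochrome P450, glutathione transferase and UDP-glycosyltransferase genes, 38 fell and 17 rose on average (40 and 23 adjusted over the list alone), with a median of -0.09. Ugt86Dd fell by 1.89, Cyp6w1 by 1.73 and Ugt35b by 0.98 on the log2 scale, while Cyp309a1 rose by 1.21. Cyp6w1 went from 159 ± 11.5 CPM in controls (SD, n = 3) to 34.6 ± 3.15 in row_RNAi1 (SD, n = 2) and 66.2 ± 4.49 in row_RNAi2 (SD, n = 3). By camera the list was lower, with an adjusted p = 0.0163, and an adjusted p = 0.304 with an estimated correlation. In row_RNAi2 alone 24 genes fell and 9 rose (32 and 17 adjusted over the list alone), and camera gave 0.0545.

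Of 35 odorant-binding and other olfactory genes, 13 fell and 5 rose on average (16 and 6 adjusted over the list alone), with a median log2 fold change of -0.49. Obp99b went from 328 ± 102 CPM in controls (SD, n = 3) to 94.2 ± 12.5 in row_RNAi1 (SD, n = 2) and 44.0 ± 3.75 in row_RNAi2 (SD, n = 3). The average log2 fold changes were -2.35 for Obp99b, -0.90 for Obp44a, -3.09 for Obp19c and -0.74 for Obp19b. In camera the adjusted p was 0.00261 for the list, 0.109 among genes of at least 5 CPM, with an adjusted p = 0.580 with an estimated correlation. A set of 11 genes with known antennal expression, chosen after seeing the data, had median levels of 6.44, 1.14 and 6.59 CPM in control replicates 1 to 3, 0.242 and 6.01 CPM in row_RNAi1, and 0.656, 0.543 and 0.712 CPM in row_RNAi2, so control replicate 2 stood below the other controls and the row_RNAi1 libraries lay apart. These 11 genes of the list had a median log2 fold change of -1.84, with 5 down. The other 24 had -0.09, with 8 down and 5 up.

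Genes of vision and of neurons were lower by small amounts on average, mainly in row_RNAi1. Of 32 photoreceptor and phototransduction genes, 8 fell on average (9 adjusted over the list alone). The opsin gene Rh5 went from 155 ± 6.46 CPM in controls (SD, n = 3) to 50.7 ± 3.25 in row_RNAi1 (SD, n = 2) and 107 ± 2.98 in row_RNAi2 (SD, n = 3). The average log2 fold changes were -1.08 for Rh5, -0.33 for the opsin gene Rh3, -0.35 for ninaB, which makes retinal from carotenoids, and -0.50 for the lipase gene inaE. Camera gave an adjusted p = 0.0132 for the list, 0.0665 with all knockdown libraries as 1 group, and an adjusted p = 0.620 with an estimated correlation. Of 41 neuronal and synaptic genes, 6 fell (5 adjusted over the list alone), with a median of -0.12. Ddc and ple, which encode the enzymes of dopamine synthesis, had -0.46 and -0.30, and ple lost its call without control replicate 1 (edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.0518). Camera gave an adjusted p = 0.00359 for the list, 0.0959 without control replicate 1, and an adjusted p = 0.620 with an estimated correlation. In row_RNAi2 alone 3 phototransduction genes (median -0.01) and 1 neuronal gene (median -0.03) fell (3 and 1 adjusted over the list alone), and neither list passed camera there (adjusted p = 0.346 and 0.710).

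Lists of energy metabolism and of female-biased transcripts were higher on average. Of 12 glycolytic genes 4 rose (4 adjusted over the list alone), among them phosphoglucose isomerase (Pgi) by 0.68 on the log2 scale and lactate dehydrogenase (ImpL3) by 1.54 in row_RNAi1 and 0.46 in row_RNAi2. Camera gave an adjusted p = 0.0207 for the list, and an adjusted p = 0.620 with an estimated correlation. Of 32 genes of oxidative phosphorylation 5 rose (3 adjusted over the list alone), with a median of 0.07, a camera adjusted p = 0.0192, and an adjusted p = 0.672 with an estimated correlation. The example with the smallest p, ATPsyngamma, had a log2 fold change of 0.21, and lost its call without control replicate 2 (adjusted p = 0.0547) or row_RNAi1 replicate 2 (0.0581) in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Both metabolic lists lost their call without control replicate 1 (camera adjusted p = 0.0764), and glycolysis also with all knockdown libraries as 1 group (0.0672). Of 4 yolk and female-biased genes 2 rose (2 adjusted over the list alone), fit by 1.38 and the yolk protein gene Yp3 by 0.63, while Yp1 had 0.11 and Yp2 -0.09. Camera gave an adjusted p = 0.0351 for them, and an adjusted p = 0.620 with an estimated correlation. This call was lost without control replicate 1 (0.153), row_RNAi1 replicate 1 (0.0973) or row_RNAi2 replicate 2 (0.0808), and among genes of at least 5 CPM (0.0731). Taken singly, glycolysis (2 genes called, 2 adjusted over the list alone, 0.199) and oxidative phosphorylation (0.112) did not pass camera in row_RNAi2, nor yolk genes in row_RNAi1 (2 genes called, 2 adjusted over the list alone, 0.179). For oxidative phosphorylation in row_RNAi2 edgeR called 0 genes, over all genes and adjusted over the list alone, with 6 at an unadjusted p under 0.05, DESeq2 1 and limma voom 0.

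The known partners of ROW in its chromatin complex were close to control levels. None of the 8 tested genes (woc, HP1c, HP1b, Ubqn, pzg, Chro, BEAF-32 and JIL-1) passed on average, nor adjusted over the list alone, in the edgeR quasi-likelihood test, where 1 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0. BEAF-32 stood at 17.7 ± 1.52 CPM in controls (SD, n = 3), 16.4 ± 0.582 in row_RNAi1 (SD, n = 2) and 18.02 ± 1.87 in row_RNAi2 (SD, n = 3), an average log2 fold change of -0.04 (SE 0.10, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.835). The average log2 fold changes of the others were 0.18 for woc, -0.05 for HP1c, -0.20 for HP1b, -0.01 for Ubqn, -0.10 for pzg, 0.10 for Chro and -0.08 for JIL-1. The paralog woc rose by 0.32 in row_RNAi1 (adjusted p = 0.0125) and had 0.03 in row_RNAi2, and this difference between lines passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0354). Of 18 insulator and architectural factor genes, Cp190 (-0.16) and su(Hw) (0.30) among them, 0 passed in the edgeR quasi-likelihood test over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0. Camera gave an adjusted p = 0.934 for the partners and 0.819 for the architectural factors.

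Further lists did not pass camera, although single members moved. Of 17 fat body and lipid genes 7 rose and 4 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.576), and average log2 fold changes were -1.02 for the acyl-CoA synthetase Acsl, 0.86 for the acetyl-CoA carboxylase ACC, -0.99 for the perilipin Lsd-1 and 0.80 for the lipase bmm. Of 14 glial genes 3 rose and 4 fell (3 and 4 adjusted over the list alone, 0.819), and the GABA transporter Gat fell by 0.58 while the trehalose transporter Tret1-1 rose by 0.43. Of 13 clock genes 2 rose and 3 fell (3 and 3 adjusted over the list alone, 0.823), with to falling by 0.78 and cwo by 0.59. Of 11 insulin and starvation genes 3 rose and 2 fell (3 and 2 adjusted over the list alone, 0.695), with Thor rising by 0.54 and the insulin-binding ImpL2 falling by 0.51. Of 10 hemocyte genes 1 rose and 3 fell (1 and 3 adjusted over the list alone, 0.192), with the prophenoloxidases PPO2 and PPO1 falling by 1.03 and 0.95. Of 38 cuticle genes 9 rose and 6 fell (10 and 6 adjusted over the list alone, 0.214), with Cpr72Ec rising by 1.17 and Cpr65Au falling by 0.66. Of 12 heat-shock genes 1 rose and 1 fell (2 and 2 adjusted over the list alone, 0.576), and Hsp22 rose by 2.28, with all its counts shared with Hsp67Bb. The falling gene, Hsp67Ba, had -0.55 and lost its call without control replicate 2 (adjusted p = 0.0893) or 3 (0.0802) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

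Of 17 muscle genes 3 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.576), with Act57B rising by 0.43. Of 86 cytosolic ribosomal protein genes 1 rose and 4 fell (1 and 2 adjusted over the list alone, 0.576), with RpS3A falling by 0.26. Of 5 digestive genes LysP rose (1 adjusted over the list alone, 0.969). Of 3 male dosage compensation genes roX1 fell by 0.45 (2 fell adjusted over the list alone, 0.137), but without control replicate 1 it stood at -0.26 (adjusted p = 0.145) and without row_RNAi1 replicate 1 at -0.40 (adjusted p = 0.0759) in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Of 8 small RNA pathway genes, Dcr-2 (-0.17) and AGO2 (-0.14) among them, 0 passed over all genes or adjusted over the list alone in the edgeR test, 2 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0 (camera adjusted p = 0.576). The male reproductive list had 1 tested gene (janB, -0.06) and the female germline list 2 (grk, -0.14, and Cp19, -0.38), so neither list was tested, and none of these genes passed in edgeR, DESeq2 or limma voom. The median, the mean and the direction of the test did not share a sign for the clock list (0.05, -0.05, down), the muscle list (0.04, -0.06, up) and the digestive list (-0.03, 1.01, up). With an estimated correlation 0 of the 24 tested lists were called in any contrast, 3 had an unadjusted p under 0.05 for the average, and fry called 9, but not neuronal genes (0.103), yolk genes (0.152) or oxidative phosphorylation (0.0664).

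Eye and body colour genes that often mark transgenes, and which both lines could carry, were read as well. The white gene w rose in row_RNAi2 by 1.16 (edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 9.25e-05) and had -0.22 in row_RNAi1. The yellow gene y rose in row_RNAi1 by 2.17 (adjusted p = 0.000124) and had -0.14 in row_RNAi2, and the differences between lines passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment for both genes (adjusted p = 2.86e-05 for w and 0.000179 for y). The vermilion gene v rose in row_RNAi1 by 0.39 (adjusted p = 0.00366) and had -0.22 in row_RNAi2, and ry rose on average by 0.34 (adjusted p = 0.00341) by the same edgeR test. On average 2 of these 4 genes rose, ry and w (3 adjusted over the list alone, camera adjusted p = 0.0562). The average of w, 0.47, kept its call without control replicate 1 or row_RNAi2 replicate 1 and lost it without any other library, for example control replicate 2 (adjusted p = 0.211 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

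Against the same controls, row_RNAi1 changed more genes than row_RNAi2. The edgeR quasi-likelihood test called 2001 genes in row_RNAi1, 1055 up and 946 down, and 1022 in row_RNAi2, 518 up and 504 down, of which 533 and 252 changed by more than 1 on the log2 scale. The median absolute log2 fold change of called genes was 0.57 and 0.55. Without row_RNAi1 replicate 1 or 2 the first count was 1226 or 1275, and with control replicate 1 as the single control the counts were 1275 and 507. The largest rises in row_RNAi1 were those of LysS, CG43680, CG44142, CG45080 and LysP, from 6.70 (LysP) to 8.38 (LysS) on the log2 scale. In row_RNAi2, CG13704 (hoka, a septate junction protein) had 364 counts against 2 in controls, a ratio of 168 (95% counting interval 46.3 to 1395) in scaled counts, while row_RNAi1 had 7 counts, a ratio of 2.72 (0.517 to 26.8). CG13947, CG44142, CG45080 and CG43680 followed, with log2 fold changes from 5.55 (CG43680) to 5.72 (CG13947), and without row_RNAi2 replicate 3 CG13947 had 4.65 and CG43680 had 4.94. Without control replicate 2 the rises were 10.11 for CG43680, 9.91 for CG44142, 8.83 for CG45080 and 7.96 for LysP in row_RNAi1, and 9.08 for CG13947, 8.41 for CG44142, 7.70 for CG45080 and 8.37 for CG43680 in row_RNAi2. The fitted falls of CG14645 (-8.75 and -8.43) and CG34220 (-7.59 and -7.87) were the largest in both lines, but rested on control replicate 3, which held 701 and 821 CPM against at most 2.43 CPM in any other library. Without that library CG34220 had 0.29 and 0.05 (adjusted p = 0.821 and 0.990, edgeR quasi-likelihood with Benjamini-Hochberg adjustment) and CG14645 was not tested. In row_RNAi1 CG14645 and CG34220 also lost their calls without row_RNAi1 replicate 1 (0.116 and 0.129) or 2 (0.0924 and 0.0870), and CG34220 lost its call in row_RNAi2 without row_RNAi2 replicate 2 (0.0566). CG8147, CG10814, CG40298 and CG4757 completed these sets.

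In row_RNAi1 8 lists passed camera. Humoral immunity (30 of 30 up, 30 adjusted over the list alone, adjusted p = 5.54e-27), Turandot (4 of 7 up, 5 adjusted over the list alone, 0.000215), oxidative phosphorylation (4 of 32 up, 4 adjusted over the list alone, 0.0229) and glycolysis (4 of 12 up, 5 adjusted over the list alone, 0.0112) were higher. Phototransduction (11 of 32 down, 13 adjusted over the list alone, 0.00133), neuronal genes (13 of 41 down, 15 adjusted over the list alone, 2.15e-05), detoxification (35 of 102 down, 37 adjusted over the list alone, 0.0192) and odorant binding (13 of 35 down, 13 adjusted over the list alone, 0.00894) were lower, although 1, 17 and 4 members of the phototransduction, detoxification and odorant-binding lists rose (1, 20 and 4 adjusted over the list alone). With an estimated correlation the adjusted p was 0.0904 for humoral immunity and Turandot, 0.711 for oxidative phosphorylation, 0.550 for glycolysis, 0.481 for phototransduction, 0.531 for neuronal genes and odorant binding, and 0.334 for detoxification. Odorant binding lost its call without row_RNAi1 replicate 1 (0.130) and detoxification without replicate 2 (0.0533). Oxidative phosphorylation lost it without control replicate 1 (0.0706) or 2 (0.0541), or without row_RNAi1 replicate 1 (0.0626) or 2 (0.0718). Among genes of at least 5 CPM oxidative phosphorylation (0.0565) and odorant binding (0.0727) lost their calls, and detoxification did with no low-count filter (0.0894).

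In row_RNAi2 6 lists passed camera, while a split of the same libraries that mixed both groups passed 9 with 0 genes called. Humoral immunity (19 of 30 up, 26 up and 1 down adjusted over the list alone, adjusted p = 8.36e-16), Turandot (4 of 7 up, 4 adjusted over the list alone, 0.00798) and yolk genes (2 of 4 up, 2 adjusted over the list alone, 0.00718) were higher. Odorant binding (12 of 35 down and 2 up, 19 and 6 adjusted over the list alone, 0.00155), hemocyte genes (4 of 10 down, 6 adjusted over the list alone, 0.000902) and cytosolic ribosomal proteins (4 of 86 down, 4 adjusted over the list alone, 0.0151) were lower, although Obp99a rose by 2.18 on the log2 scale. With an estimated correlation the adjusted p was 0.276 for humoral immunity and Turandot, 0.526 for yolk genes, 0.457 for odorant binding, 0.394 for hemocyte genes and 0.950 for ribosomal proteins. Yolk genes lost their call without control replicate 1 (0.0539). Ribosomal proteins lost it without control replicate 2 (0.126) or 3 (0.886) or row_RNAi2 replicate 3 (0.888), and with the replicate number as a block (0.0506). Odorant binding lost its call among genes of at least 5 CPM (0.197), and fry gave 0.0607 for it, 0.208 for yolk genes and 0.720 for ribosomal proteins.

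The direct comparison of the lines asks where the knockdowns differ. The Osiris family gene Osi2 stood at 21.2 ± 1.49 CPM in controls (SD, n = 3), 1.09 ± 0.257 in row_RNAi1 (SD, n = 2) and 21.05 ± 1.09 in row_RNAi2 (SD, n = 3). The insulin-responsive glucosidase gene tobi stood at 128.5 ± 23.7, 53.7 ± 20.5 and 361 ± 22.6 CPM, and the odorant-binding gene Obp99a at 242 ± 65.4, 179 ± 80.9 and 1101 ± 97.3 CPM. CG4757 fell further in row_RNAi2, with 38.6 ± 4.49, 12.6 ± 2.14 and 0.891 ± 0.652 CPM. In all, 1068 genes differed between the lines in the edgeR quasi-likelihood test, 470 higher and 598 lower in row_RNAi2, and 555 without either row_RNAi1 library. Among the named genes the log2 differences, row_RNAi2 minus row_RNAi1, were 5.89 for CG13704, 4.24 for Osi2, 2.89 for CG7509, 2.75 for tobi, 2.62 for Obp99a, -3.62 for CG4757, -2.93 for CG43920, -2.87 for CG10924, -2.72 for LysS and -2.30 for the infection-responsive gene edin. The row_RNAi1 libraries differed in some of these genes. Without row_RNAi1 replicate 1, edin had -0.36 (adjusted p = 0.843) and CG43920 -1.85 (0.0789), and without replicate 2 CG10924 had -1.92, edin -3.10 and CG43920 -3.53 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Without row_RNAi2 replicate 2 edin had -1.90 (0.0955) and LysS -3.36 by the same edgeR test. DESeq2 called neither edin (0.348) nor CG43920 (0.166), and limma voom did not call edin (0.0877).

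Between the lines 7 lists passed camera, with row_RNAi2 higher for phototransduction (7 of 32 up, 11 adjusted over the list alone, adjusted p = 0.000493) and neuronal genes (6 of 41 up, 11 adjusted over the list alone, 4.69e-07). It was lower for humoral immunity (20 of 30, 27 adjusted over the list alone, 7.20e-23), Turandot (4 of 7, 4 adjusted over the list alone, 0.00328), hemocyte genes (4 of 10, 5 adjusted over the list alone, 0.0367), glycolysis (3 of 12, 3 adjusted over the list alone, 0.0183) and cytosolic ribosomal proteins (2 of 86, none adjusted over the list alone, 0.00592). Against these directions, 1 phototransduction and 2 hemocyte genes went the other way (2 and 2 adjusted over the list alone, and 1 Turandot gene). Drs differed by -1.31 and Def by -0.80, and Rh5 by 1.07 on the log2 scale. With an estimated correlation the adjusted p was 0.195 for humoral immunity and Turandot, 0.494 for phototransduction, 0.511 for neuronal genes, 0.515 for hemocyte genes and glycolysis, and 0.739 for ribosomal proteins.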

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

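The tests of a single response of unequal strength, of a shared source for the genes high in control replicate 2, of material mixed into that library, of the correlation among antennal markers, and of antennal level as a covariate were chosen only after the results were seen.

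The results below stood out because the change against control differed between the lines, by the edgeR quasi-likelihood test of row_RNAi2 minus row_RNAi1 with Benjamini-Hochberg adjustment. In all 1068 genes differed. Genes that rose in both lines but less in row_RNAi2 were LysS (-2.72), LysP (-2.29), Cpr64Ac (-1.95), CG33109 (-1.92), CG43680 (-1.73), CG44142 (-1.50) and CG43679 (-1.21), on the log2 scale. Genes that fell in both lines but less in row_RNAi2 were CG40298 (3.12), CG3270 (2.25), CG9507 (2.21), CG40470 (2.04), CG8147 (1.51), CG3397 (0.96) and CG10962 (0.69), while CG4757 fell further in row_RNAi2 (-3.62). CG13704 (5.89), Osi2 (4.24), CG7509 (2.89), tobi (2.75) and Obp99a (2.62) were higher in row_RNAi2, and CG43920 (-2.93), CG10924 (-2.87) and edin (-2.30) were lower there. Without row_RNAi1 replicate 1 edin had -0.36 (adjusted p = 0.843) and CG43920 -1.85 (0.0789), without replicate 2 CG10924 had -1.92, edin -3.10 and CG43920 -3.53, and without row_RNAi2 replicate 2 edin had -1.90 (0.0955), all by the edgeR test, and either row_RNAi1 library left out gave 555 genes. Lists that camera separated had median differences of -1.14 (humoral immunity), -1.01 (Turandot), -0.22 (hemocyte), -0.0737 (cytosolic ribosome), -0.0596 (glycolysis), 0.15 (phototransduction) and 0.17 (neuronal), and none of these 7 passed with an estimated correlation (smallest adjusted p = 0.195).

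More genes changed in row_RNAi1, a ratio of 1.96 between the counts of genes, and with all libraries thinned to the smallest total, the ratio stayed at 1.80 in the median of 10 thinnings (1.78 to 1.86), which argues against sequencing depth as the whole cause. A single response of unequal strength may explain part of it. Of the 1068 genes, 828 were called in row_RNAi1 with the larger change there, which partly restates that this line had more calls. Such a response needs the larger change there and the same sign in both lines, and only 613 of the 1068 had both. The test itself left it open, since 10.3% (exact 95% interval 8.54 to 12.3) were called in row_RNAi2 with a larger change there, too close to the 10% set to decide. Linked genetic background could add to it: among genes called in 1 line and also between the lines, neighbours were called together 1.57 times as often as random placement gives (1.64 for the 538 genes of row_RNAi1 and 4.36 for the 81 of row_RNAi2, the latter from 3 pairs), against 1.91 for genes called in both lines (1.54 to 2.44 against 95% of random placements), so background and knockdown cannot be told apart for these genes. The line itself, its hairpin and its insertion remain open as untested explanations.

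Control replicate 2 carried the 9 genes that rose in all knockdown libraries at 15.7 CPM in the median, against 0.525 and 0.447 CPM in the other controls. A shared source of RNA, such as a tissue or state present in unequal amounts, is a candidate explanation. The 9 genes correlated at 0.820 over the knockdown libraries after centring within each line, above all 1000 random lists (95% between -0.311 and 0.417). Those lists were matched on mean expression but not on variability, and the 9 genes were chosen from these data. A shared regulator would also give the same correlation, so it does not decide the source. Knockdown material mixed into this library could also give the pattern: genes at least 8 times higher in row_RNAi2 than in the other controls stood there at 5.76% of their row_RNAi2 level in the median (95% bootstrap interval 4.28 to 7.97), but 9 of these 15 genes are the 9 themselves. The other genes went apart, with lcs at 12.9% and CG13704 at 0.293%, and for row_RNAi1 the median over 31 genes was 0.609% (0 to 2.22) against 1.49% to 6.77% for the 9, so mixing and other sources cannot be told apart for these genes. Without this library the average log2 fold change was larger, at 9.16 for CG44142 and 8.27 for CG45080. Because the 9 genes were chosen as high in this control, leaving it out had to raise the change, so these values do not test the rise.

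The median of 11 antennal markers was low in control replicate 2, row_RNAi1 replicate 1 and all row_RNAi2 libraries, and their correlation of 0.770 within groups restates this, since the markers were chosen after these levels were seen. Fewer antennae in some libraries could lower some of them, but Orco (2.996 CPM against 2.63 and 3.01), lush (2.58 against 1.71 and 2.79), Obp28a (22.7 against 26.9 and 30.1) and Obp69a (4.03 against 4.20 and 6.59) were not low in control replicate 2 in the same way. With the antennal level of each library as a covariate, the median average log2 fold change of the 8 falling genes outside the markers, among them Obp99b, Obp44a, Obp19c and Obp19b, went from -0.82 to -0.79 (95% bootstrap interval -2.02 to -0.54) and all 8 were still called. It moved the markers' median from -1.84 to -0.24. The markers Orco (-1.38), lush (-2.11), Obp19a (-2.14) and Obp28a (-0.57) were also still called with it. The covariate thus does not hold all antennal content. In row_RNAi1 replicate 2 the marker median was near control (6.01 CPM), yet all 8 genes lay below every control. Obp44a stood at 689 CPM there (655 in replicate 1) and Obp99b at 103 (85.4). Control replicate 2, with low markers, lay above every knockdown library for all 8. The 8 genes were chosen as called lower in these same libraries, which favours genes on 1 side of all controls. These positions therefore do not test antennal content as a cause. The rule set for the covariate left it open, because called markers were still called. Among the controls, Obp99b (225 CPM against 329 and 429), Obp44a, Obp19d and Obp8a were lowest in control replicate 2. Obp19b, Obp83cd, Obp56g and Obp19c were not. Orco (1.21 CPM) and lush (0.982) were low in row_RNAi1 replicate 2, so the marker median does not settle the antennal content of that library. As a list, the 24 genes outside the markers had a camera p of 0.0237 and a median of -0.09, which decides neither way.

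Other splits of the libraries were fitted to ask how often another grouping gives as many calls. Of 100 splits of the 8 libraries, 1, the real split, gave as many genes on average (1680, next 812). Regrouping these libraries thus did not give that count, but the splits cannot separate knockdown from line background or from how the flies were collected. For lists 1 split gave as many (9, next 8), a lead of 1 list. The real count was 6 lists without control replicate 1 and 0 with an estimated correlation (by camera, 3 with an unadjusted p under 0.05, and 9 by fry), and the other splits were not refitted with these settings. The next split for genes grouped both row_RNAi1 libraries with row_RNAi2 replicate 1, and kept all 3 controls together as a group. Those that followed, with 721 and 709 genes, also kept the 3 controls together. Splits that broke up the controls gave at most 90 genes. For row_RNAi2 the 10 splits are too few for a share under 0.05: the real split gave 1022 genes (next 0; 1 split as large) and 6 lists (next 9; 2 splits as large). With 0 genes called, other splits still passed up to 9 lists in row_RNAi2 and 8 on average. The number of lists passing camera at the preset correlation therefore does not by itself set the real groups apart.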

How the results depend on the processing

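The collapse of symbols with identical counts, the fit without control replicates 2 and 3, and the split of the controls were chosen only after the results were seen.

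The row transcript kept its call under all alternatives that were run. With all knockdown libraries as 1 group, 834 genes changed on average instead of 1680, all of them among the 1680. That fit counts differences between the lines as spread, which the 3-group model does not. The correlation between the lines went from 0.775 to 0.540 with no low-count filter and 0.573 with DESeq2. Without control replicates 2 and 3, which leaves a single control assumed to vary like the other groups, the counts were 1275 genes in row_RNAi1 (1200 of them shared with the full set), 507 in row_RNAi2 (482), 883 on average (835) and 424 in both lines (403). With the controls split between the lines the median over 6 ways was 487.5 shared genes and a correlation of 0.604. Leaving out 1 library at a time gave 1226 to 2150 genes in row_RNAi1, lowest without row_RNAi1 replicate 1 (1275 without replicate 2), and 555 to 1110 genes between the lines, lowest without either row_RNAi1 library. An estimated correlation left 0 lists in row_RNAi1, 0 in row_RNAi2 and 0 on average by camera, where 3, 2 and 3 lists had an unadjusted p under 0.05 and fry called 12, 5 and 9. The cause was not tested for these shifts, except that removing libraries and widening the groups change the spread that the tests use.

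Among named genes, CG34220 turned from -7.59 in row_RNAi1 to 0.29 and from -7.87 in row_RNAi2 to 0.0453 without control replicate 3, which held most of its counts, and ran from -9.52 and -8.45 at the other end over the libraries left out. Of 2618 values of 155 named results under alternatives, 2467 kept direction and call, 136 lost the call, 13 gained it and 2 turned direction. A further 5 had no adjusted p in DESeq2.

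Replicate numbers as a block gave 1815, 939 and 1559 genes in row_RNAi1, row_RNAi2 and on average. Libraries sharing a number had no shared deviation that pairing would need (correlations from -0.13 to 0.0563 over 7 pairs), and 2 of 8 libraries were closest to their own number.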

Other observations

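The search of gene families by symbol was chosen only after the results were seen, while the test of one-carbon genes was set before its values were read.

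Several enzymes of folate and glycine metabolism, picked after their values were seen, rose on average. The dehydrogenases pug and Nmdmc, which interconvert folate-bound carbon units, rose by 1.59 and 1.76 on average on the log2 scale, the glycine methyltransferase Gnmt by 1.08 and CG3999, glycine decarboxylase, by 2.05, although Gnmt had only 0.05 in row_RNAi2. Of 10 related genes not looked at before the test, 4 rose, among them the serine hydroxymethyltransferase CG3011 by 0.98 and sarcosine dehydrogenase (Sardh) by 1.76, and 2 fell, among them CG8665, which fell by 1.81. Of the 4, CG3011 (0.73), CG6415 (0.71) and Sardh (1.37) also rose in row_RNAi2, but Ahcy13 had 1.02 in row_RNAi1 and 0.06 in row_RNAi2. A rise of one-carbon metabolism as a group may be part of the knockdown response. For the 10 genes on average, camera gave an unadjusted p = 0.00128, but p = 0.103 with an estimated correlation. The same pattern in new libraries with separate controls for each UAS line would test it.

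Searching 76 families of symbols gave 5 with a camera adjusted p under 0.05 on average: IM peptides (7 of 8 up, adjusted p = 7.84e-11), Ugt (4 of 8 down, 0.0205), GstE (9 of 13 down and 1 up, 0.0205), serpins (5 of 14 up, 0.0205) and Obp (11 of 29 down and 5 up, 0.0421). With an estimated correlation none of these families passed (smallest adjusted p = 0.651). All 8 IM peptides rose in row_RNAi1, while in row_RNAi2 5 rose and 1 fell. Of the serpins, inhibitors of proteases such as those of the immune cascades, Spn42Dd rose by 0.74, Spn88Eb by 0.75 and Spn27A by 0.58 on the log2 scale, and none of these 3 was in the fixed lists. The other 4 families overlap lists already described.

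CG14645 and CG34220 stood at 701 and 821 CPM in control replicate 3 and at no more than 2.43 CPM in any other library. No other library here held enough of these transcripts to have supplied them, and the reason was not tested.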
